A study of Homo sapiens with 12 samples.

How the data were processed

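Total RNA was extracted with Trizol, labelled as biotinylated cRNA and hybridised to Illumina HT-12 bead arrays, per the labels, which name GenomeStudio without a version. The deposited table of unnormalised values holds, for each of 47322 probes and 12 arrays, the mean bead intensity on the linear scale, which was neither background-subtracted nor normalised between arrays. Per the file headers, it also holds a detection p-value for each probe and array, the number of beads, and a bead standard error. The 12 columns of bead standard errors were not used. The series matrix deposited by the authors holds a processed intensity on the linear scale. Its 12 columns had medians of 7.54 to 7.58 and 28.2% to 28.3% of values at or below 0, nearly equal distributions, and the same ranking of probes as the signal of the same array (Spearman correlation 1). The steps that led to it are not stated, and it served as an alternative only. Each array's column was joined to its group through the sample descriptions, and this ranking was used to check the joining.

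Probes were matched to genes through the array annotation by Entrez ID, and symbols were brought up to date with a table of RefSeq genes of assembly GRCh38.p14. Of the 47322 probes, 30113 had 1 gene, 8 had several and 17201 had none, and 30074 of those with 1 gene matched a current gene. Probes with several genes or none were left out of the gene tests.

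The signal was corrected for background, quantile normalised and put on the log2 scale with neqc of limma 3.58.1 in R 4.3.3, which estimates background from the detection p-values, with an offset of 16. A probe was kept if its detection p-value was under 0.01 on at least 3 of the 12 arrays, which held for 18427 probes, 14790 of them with 1 gene. Each gene was represented by its detected probe with the highest mean over all arrays, which gave 11280 genes, 2867 of them with more than 1 detected probe. A gene was below background in a group when its probe was detected on none of the 3 arrays.

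All 12 arrays were fitted in 1 linear model of 4 groups with limma (lmFit and eBayes), and the 6 differences between groups were tested with limma's moderated statistic, two-sided. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 and at least a 2-fold change, when detected on at least 2 arrays of the higher group. Where 1 group was below background, the fold is given as a lower bound, with the group below background set at the detection floor of its arrays, the lowest normalised level that passes the detection threshold. No fold is given where both groups were below background. Another detected probe of a called gene pointed the opposite way for 25 of 408 called genes with several probes between NPC-NC and LSB, 52 of 564 between MS5-NC and LSB, 23 of 507 between sox10-NC and LSB, 0 of 3 between NPC-NC and MS5-NC, 23 of 386 between NPC-NC and sox10-NC and 34 of 462 between MS5-NC and sox10-NC, and by at least 2-fold for at most 1 in each.

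Lists of genes for 24 cell types, pathways and responses were fixed before the data were examined, as were the test, its thresholds, the rule for named genes and all alternatives but 1. They were neural crest specifiers, neural crest surface and migration, CNS neuroepithelium, pluripotency, roof plate and dorsal neural tube, HOX paralogs 1 to 4 and 5 to 13, Schwann cell and glial precursor, melanocyte, sensory neuron, autonomic and enteric neuron, pan-neuronal, mesenchyme and extracellular matrix, epithelial and epidermal, mesoderm and muscle, epithelial to mesenchymal transition, Wnt target, BMP target, Notch pathway, proliferation, immediate early, integrated stress response, hypoxia and cholesterol synthesis. The 20 lists with at least 5 measured members were tested in each comparison with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over 120 tests. Camera with an estimated correlation and limma's fry were run as alternatives. A count adjusted over the list alone applies the adjustment to the list's measured members only. Where a list's members lay below background in 1 group, its median is given also with these members at their bounds.

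Genes were named by a rule. It takes a marker panel of 13 genes whatever their values, up to 6 called genes with the largest rise and 6 with the largest fall per comparison among genes detected on all arrays of both groups without overlap, up to 3 called members in each direction of each list that passed or had at least 1 in 3 measured members called, and up to 6 genes in each direction that were shared by 3 comparisons or set apart in NPC-NC, among genes detected on all arrays. Uncharacterised symbols were skipped among the largest and shared changes. A gene named for 1 comparison could be named in another. The remaining called genes of the NPC-NC and MS5-NC comparison, among them set-apart genes that some arrays did not detect, and the members SOX8, SOX9 and ZIC1 given for NPC-NC against LSB, were named after their values were seen. Of 374 named calls, 21 concern genes that were no longer tested when an array of the only group that detected them was left out.

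Comparisons that share a group were set beside 100 simulated sets of groups without changes. The test was checked on simulated data of 11280 genes with 200 changed genes in 20 runs. It recovered 45.1% to 47.7% of 2-fold changes, 95.1% to 96.5% of 2.83-fold changes and at least 99.8% of 4-fold changes, and called 6.6 to 7.6 unchanged genes per run. Camera gave a p under 0.05 for 3.4% of 1000 random lists. Random lists lack the correlation between genes of a real list, so this value does not check the preset correlation. The alternatives were no background correction, the authors' processed values, an offset of 50, a detection threshold of 0.05, no detection filter, the mean over a gene's detected probes, a fit of the compared groups only, array weights, the replicate number as a block, no minimum fold, an adjusted p under 0.01, and each array left out in turn. Leaving out NPC-NC array 1 and MS5-NC array 1 together was added after the values were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.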

Results

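Gene expression was measured on Illumina HT-12 bead arrays in 12 samples derived from H9, a human embryonic stem cell line. They formed 4 groups of 3 arrays, numbered as biological replicates. LSB held unsorted neuroepithelial cells at day 11. MS5-NC held cells induced on MS5, a mouse stromal feeder line, collected at day 35. NPC-NC held cells induced without feeders and collected at day 18. Both MS5-NC and NPC-NC were sorted for HNK1, a carbohydrate epitope, and for p75, the receptor encoded by NGFR. The group called sox10-NC was induced with Wnt, carried a SOX10 reporter, and was sorted at day 11. Each array reported 47322 probes, of which 14616 to 17101 (30.9% to 36.1%) were detected above background. The median probe signal was 93.4 to 114 intensity units, read from a median of 18 to 22 beads per probe. The number of arrays limits the precision of every value given here. Log2 changes are given with their SE from the fit of all 12 arrays, with n = 3 arrays per group, and log2 levels with their SD over 3 arrays. The size of a fold change depended on background correction, and without it the named folds came to a median of 0.577 times the values given here.

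The arrays of each group resembled each other most, apart from the MS5-NC and NPC-NC arrays, whose profiles overlapped. Across the genes tested, the Pearson correlation between MS5-NC and NPC-NC arrays was 0.947 to 0.970, against 0.962 to 0.969 among MS5-NC arrays and 0.956 to 0.975 among NPC-NC arrays. It was 0.975 to 0.980 among LSB arrays and 0.943 to 0.962 among sox10-NC arrays. LSB arrays correlated with NPC-NC arrays at 0.883 to 0.912, with MS5-NC arrays at 0.849 to 0.893 and with sox10-NC arrays at 0.848 to 0.881. Genes are not independent replicates, so these coefficients describe profiles and carry no test. The first principal component held 40.0% of the variance and set the sox10-NC arrays apart from the MS5-NC and NPC-NC arrays. The second held 31.0% and set LSB apart from the sorted groups. On the third, with 6.70%, NPC-NC arrays 2 and 3 lay at 24.4 and 25.1 and NPC-NC array 1 at −14.6. There MS5-NC array 1 lay at −2.11 and MS5-NC arrays 2 and 3 at −12.6 and −12.9. The same axis spread the sox10-NC arrays as widely, with array 1 at −24.5, array 2 at 25.0 and array 3 at −2.44.

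**Figure D1:**
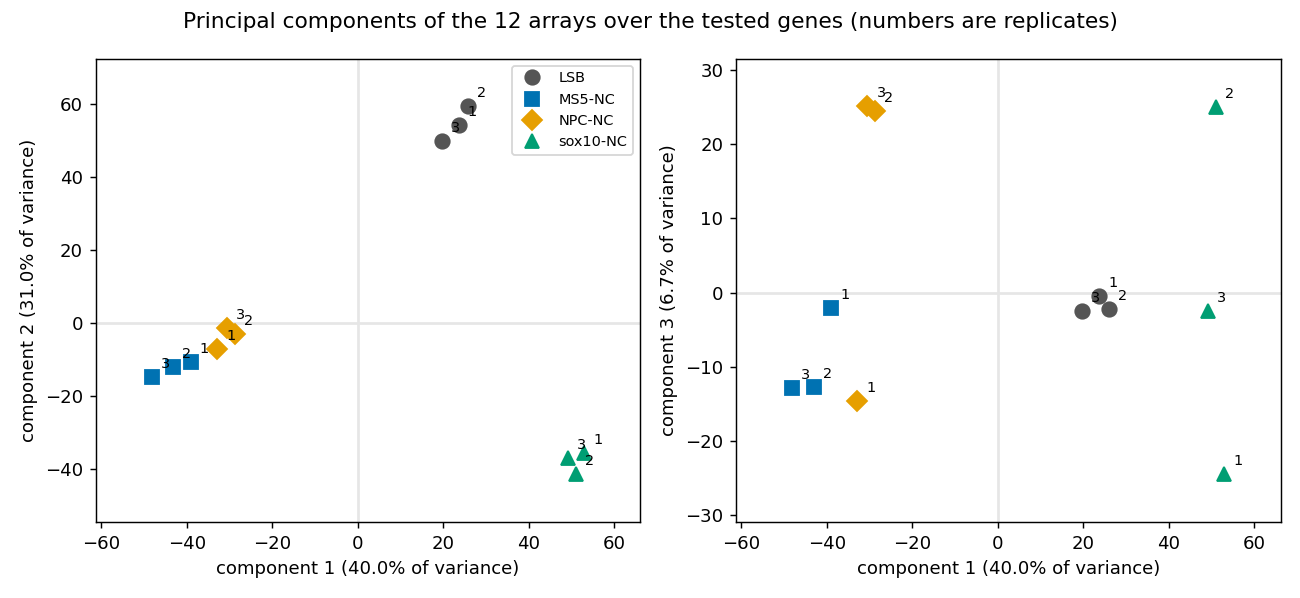
Position of the 12 arrays on the first 3 principal components of the log2 values, 1 point per array, coloured by group, with the percent of variance on each axis. The first component, with 40.0%, parts the sox10-NC arrays from the MS5-NC and NPC-NC arrays, and NPC-NC array 1 lies at −14.6 on the third component, away from NPC-NC arrays 2 and 3, while sox10-NC arrays 1 and 2 lie at −24.5 and 25.0 on it.

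Neural crest marker genes were abundant on the sox10-NC arrays and low or below background in the other groups. SOX10, a transcription factor of migrating neural crest, had a log2 level of 10.72 ± 0.23 in sox10-NC and was below background on all arrays of LSB, MS5-NC and NPC-NC. The same held for TFAP2B, a neural crest transcription factor, with 10.01 ± 0.31 in sox10-NC, and for FOXD3, an early neural crest factor, with 6.76 ± 0.52. The sox10-NC cells were sorted by a SOX10 reporter, so their high SOX10 level follows from the sort. ERBB3, a neuregulin receptor of neural crest and glia, had 10.44 ± 0.15 in sox10-NC, 5.69 ± 0.50 in LSB, 5.02 ± 0.61 in MS5-NC and 5.54 ± 0.51 in NPC-NC. TFAP2A, an activator of neural crest genes, had 9.61 ± 0.32 in sox10-NC, 5.56 ± 0.64 in LSB, 5.24 ± 0.51 in MS5-NC and 5.38 ± 0.74 in NPC-NC. SNAI2, a repressor of epithelial cadherins, had 9.36 ± 0.40 in sox10-NC, 6.09 ± 0.13 in LSB, 5.45 ± 0.29 in MS5-NC and 5.37 ± 0.63 in NPC-NC. As SOX10, TFAP2B and FOXD3 were detected in sox10-NC alone, they left the tested set when a sox10-NC array was left out. PAX3, a factor of the neural plate border, had 6.52 ± 0.21 in sox10-NC and its probe was detected on 1 of the 9 arrays of the other groups, in MS5-NC, while another PAX3 probe was detected on 1 LSB array.

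NGFR, which encodes the sorted p75 receptor, had a log2 level of 6.78 ± 0.57 in sox10-NC, where all 3 arrays detected it. It was detected on 2 of 3 NPC-NC arrays, with a mean of 5.33 ± 0.35, on none of the 3 MS5-NC arrays (4.65 ± 0.09) and on 1 of 3 LSB arrays (4.87 ± 0.33). PAX6, a transcription factor of the neural plate and forebrain, had 9.04 ± 0.07 in LSB, 9.03 ± 0.14 in MS5-NC and 8.55 ± 0.72 in NPC-NC, and was below background on every sox10-NC array. OTX2, a forebrain and midbrain homeobox factor, had 9.98 ± 0.08 in LSB, 10.27 ± 0.31 in MS5-NC, 10.12 ± 0.31 in NPC-NC and 6.74 ± 0.25 in sox10-NC. Its other probes were below background in sox10-NC, at 4.80 and 4.98, and lay at 8.07 to 8.56 in the other groups. LHX2, a selector gene of the cortex and eye field, had 10.39 ± 0.06, 11.75 ± 0.27 and 11.71 ± 0.48 in LSB, MS5-NC and NPC-NC, and was below background in sox10-NC. SOX1, a neuroepithelial factor, and POU5F1, a factor of pluripotent cells, were not detected on 3 arrays and were not tested.

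**Figure D2:**
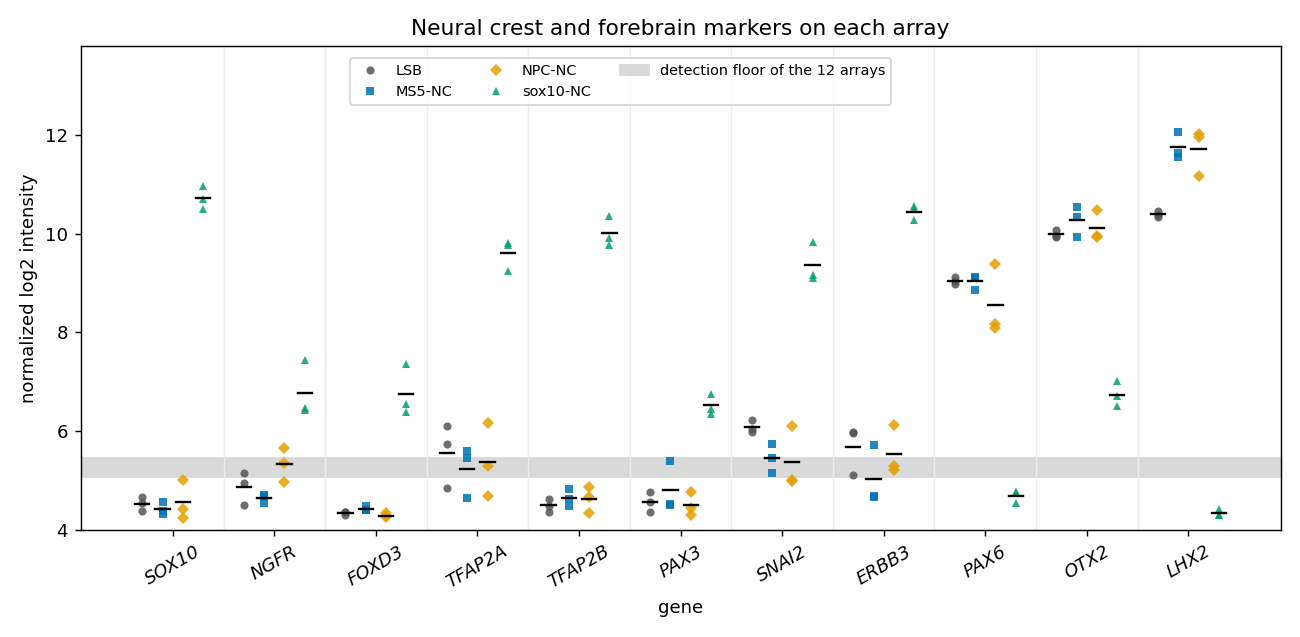
Log2 expression of the 11 tested genes of the marker panel on each of the 12 arrays, with a bar at each group's mean (n = 3) and with the range of the arrays' detection floors in grey. SOX10 lies within or below the floor in LSB, MS5-NC and NPC-NC and at 10.72 in sox10-NC, while LHX2 lies at 10.39 to 11.75 in the first 3 groups and below the floor in sox10-NC.

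The comparison of NPC-NC with LSB set sorted cells of the feeder-free route at day 18 beside unsorted neuroepithelial cells at day 11. Induction, sorting and days in culture differed together, so their effects cannot be told apart. EOMES, a T-box factor of mesendoderm and of cortical intermediate progenitors, was 27.9-fold higher (log2 4.80 ± 0.24, adjusted p = 7.95e-10). ZIC4, a zinc finger factor of the dorsal neural tube, was 12.9-fold higher (3.69 ± 0.30, adjusted p = 1.45e-07) and DCX, a microtubule protein of migrating neurons, 7.92-fold higher (2.99 ± 0.29, adjusted p = 1.15e-06). IGFBP3, which binds insulin-like growth factors, was 17.7-fold lower (-4.14 ± 0.29, adjusted p = 2.84e-08), and LIN28A, an RNA-binding protein of pluripotent cells, 15.4-fold lower (-3.95 ± 0.58, adjusted p = 7.99e-05). For each of these genes, all 3 NPC-NC arrays lay on the same side of all 3 LSB arrays. The rule for the largest rises and falls requires this separation, so it adds no support.

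Of 21 measured pan-neuronal genes, 17 were higher in NPC-NC and 0 lower (adjusted over the list alone, 17 and 0), with median log2 change 2.14 (camera adjusted p = 1.42e-11, and adjusted p = 0.147 with an estimated correlation). They included DCX and NEFM, a neurofilament, with 2.45 ± 0.44. In the roof plate and dorsal neural tube list, 4 of 9 members were higher (adjusted over the list alone, 4 and 0), with median log2 change 0.29, or 1.25 with members below background at their bounds (camera adjusted p = 0.00833, and adjusted p = 0.242 with an estimated correlation). RSPO3, a secreted Wnt agonist, rose by 2.61 ± 0.27, and RSPO1, a related agonist below background in LSB, was at least 5.30-fold higher. The Notch pathway list had 6 of 15 members higher (adjusted over the list alone, 6 and 0; camera adjusted p = 0.00155, and adjusted p = 0.356 with an estimated correlation), among them the receptors NOTCH1 (2.83 ± 0.30) and NOTCH3 (2.33 ± 0.26) and HES6, a transcriptional repressor (2.43 ± 0.28). Of the mesenchyme and extracellular matrix genes, 10 of 19 were higher and 2 lower (adjusted over the list alone, 10 and 2), with median log2 change 1.38, or 1.12 with members below background at their bounds (camera adjusted p = 0.00155, and adjusted p = 0.339 with an estimated correlation). COL6A1, a collagen VI chain, rose by 2.86 ± 0.27, while TAGLN, a smooth muscle actin-binding protein, fell by 1.84 ± 0.24. Cholesterol synthesis genes were higher for 6 of 12 members (adjusted over the list alone, 6 and 0; camera adjusted p = 1.27e-04, and adjusted p = 0.297 with an estimated correlation), with DHCR7, the enzyme of the last step, at 2.08 ± 0.27.

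Immediate early genes were higher for 7 of 13 members (adjusted over the list alone, 7 and 0; camera adjusted p = 0.00485, and adjusted p = 0.398 with an estimated correlation), with FOS, a subunit of AP-1, at 3.43 ± 0.41 and EGR1 at 2.39 ± 0.40. LSB was the only unsorted group, so this list differed along with sorting. Wnt target genes were higher for 4 of 13 members (adjusted over the list alone, 4 and 0; camera adjusted p = 0.00841, and adjusted p = 0.351 with an estimated correlation). Epithelial genes were lower for 8 of 12 members (adjusted over the list alone, 0 and 8), with median log2 change -1.52, or -1.01 with members below background at their bounds (camera adjusted p = 2.69e-07, and adjusted p = 0.129 with an estimated correlation). CDH1, which encodes E-cadherin, was below background in NPC-NC and at least 6.61-fold lower, and KRT19, a keratin of simple epithelia, fell by 2.09 ± 0.33. Pluripotency genes were lower for 3 of 8 members (adjusted over the list alone, 0 and 3; camera adjusted p = 0.0229, and adjusted p = 0.471 with an estimated correlation). The proliferation list had no called member among 24 (adjusted over the list alone, 0 and 0) and median log2 change -0.32 (camera adjusted p = 0.0329, and adjusted p = 0.380 with an estimated correlation).

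Neural crest specifier genes did not shift as a list between NPC-NC and LSB, with 3 of 18 members higher (adjusted over the list alone, 3 and 0), median log2 change 0.07, or 0.16 with members below background at their bounds and adjusted p = 0.535. The 3 were SOX8, SOX9 and ZIC1, which are also expressed in glia, cartilage or the dorsal neural tube. In the neural crest surface and migration list 4 members were higher and 1 lower of 15 (adjusted over the list alone, 4 and 1; camera adjusted p = 0.225, and fry adjusted p = 0.00814). The higher ones were CDH6, EDNRB, GFRA1 and NRP1, which encode a cadherin, an endothelin receptor, a GDNF family receptor and a neuropilin, and the lower one CDH11. CDH6 (1.60 ± 0.23) and EDNRB (1.52 ± 0.26) were no longer called as the mean over each gene's probes, and CDH6 and CDH11 without background correction. The CDH11 call also ended without LSB array 2, NPC-NC array 2 or NPC-NC array 3. These checks took at most 3 higher members of a list, so they did not cover all 4 higher genes. The CNS neuroepithelium list moved both ways, with 6 members higher and 5 lower of 23 (adjusted over the list alone, 6 and 5; camera adjusted p = 0.976). Its median of 0.14 and mean of 0.01 were positive while the test pointed down. EMX2, a cortical homeobox factor, was higher by 1.95 ± 0.22, and RAX and SIX6, factors of the eye field, fell by 2.79 ± 0.28 and 2.79 ± 0.32. Schwann cell and glial precursor genes were higher for 2 and lower for 1 of 9 (adjusted over the list alone, 2 and 1; adjusted p = 0.440). In all, 1696 of 11280 genes were called between NPC-NC and LSB, 1150 higher and 546 lower, and in 272 of them 1 group was below background. Without background correction 533 were called, 78.8% of them higher against 67.8%, and with an offset of 50 in place of 16 there were 950.

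The comparison of MS5-NC with LSB put feeder-induced, sorted cells at day 35 beside the same neuroepithelial stage at day 11. Induction, sorting and days in culture again differed together. EOMES was 31.8-fold higher (log2 4.99 ± 0.24, adjusted p = 1.50e-10), GNRH1, which encodes gonadotropin-releasing hormone, 26.2-fold higher (4.71 ± 0.27, adjusted p = 1.43e-09), and CNTN2, an axonal adhesion protein, 20.5-fold higher (4.36 ± 0.33, adjusted p = 5.18e-08). MT1F, a metal-binding metallothionein, was 14.0-fold lower (-3.81 ± 0.29, adjusted p = 5.61e-08), and ANXA1, a phospholipid-binding annexin, 9.45-fold lower (-3.24 ± 0.31, adjusted p = 6.29e-07). All 3 MS5-NC arrays lay on the same side of all 3 LSB arrays for each of these genes, a separation that the rule requires.

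Pan-neuronal genes were higher for 18 of 21 members and lower for 0 (adjusted over the list alone, 18 and 0), with median log2 change 2.26 (camera adjusted p = 1.34e-11, and adjusted p = 0.147 with an estimated correlation). DCX rose by 3.56 ± 0.29 and GNG3, a neuronal G protein subunit, by 3.24 ± 0.27. The sensory neuron list had 4 of 7 members higher (adjusted over the list alone, 5 and 0), with median log2 change 1.20, or 1.02 with members below background at their bounds (camera adjusted p = 0.0284, and adjusted p = 0.380 with an estimated correlation). Its member ISL1, a LIM homeobox factor, was 9.40-fold higher (3.23 ± 0.43). Among mesenchyme and matrix genes, 13 of 19 were higher and 2 lower (adjusted over the list alone, 13 and 2), with median log2 change 1.40, or 1.09 with members below background at their bounds (camera adjusted p = 0.00175, and adjusted p = 0.339 with an estimated correlation), and COL3A1, a fibrillar collagen, rose by 3.26 ± 0.31. Roof plate genes were higher for 5 of 9 members (adjusted over the list alone, 5 and 0; camera adjusted p = 6.92e-04, and adjusted p = 0.146 with an estimated correlation). The Notch pathway list had 6 of 15 higher (adjusted over the list alone, 6 and 0; camera adjusted p = 0.0284, and adjusted p = 0.471 with an estimated correlation), the Wnt target list 5 of 13 (adjusted over the list alone, 5 and 0; camera adjusted p = 0.0396, and adjusted p = 0.423 with an estimated correlation), and the cholesterol synthesis list 5 of 12 (adjusted over the list alone, 5 and 0; camera adjusted p = 0.00155, and adjusted p = 0.360 with an estimated correlation). TH, the rate-limiting enzyme of catecholamine synthesis, was below background in LSB and at least 16.1-fold higher in MS5-NC.

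Immediate early genes were higher for 6 of 13 members in MS5-NC, again along with sorting (adjusted over the list alone, 6 and 0; camera adjusted p = 0.00334, and adjusted p = 0.380 with an estimated correlation), and FOS was 17.7-fold higher. Epithelial genes were lower for 8 of 12 (adjusted over the list alone, 0 and 8; camera adjusted p = 4.99e-06, and adjusted p = 0.147 with an estimated correlation), and pluripotency genes for 5 of 8 (adjusted over the list alone, 0 and 5; camera adjusted p = 0.00289, and adjusted p = 0.380 with an estimated correlation). The proliferation list had 1 lower member of 24 (adjusted over the list alone, 0 and 1), with median log2 change -0.46 (camera adjusted p = 0.0402, and adjusted p = 0.380 with an estimated correlation). In the neural crest specifier list, 3 members were higher and 1 lower of 18 (adjusted over the list alone, 3 and 1; camera adjusted p = 0.801). In the neural crest surface and migration list the same 5 genes were called the same way as in NPC-NC, 4 higher and 1 lower of 15 (adjusted over the list alone, 4 and 1; camera adjusted p = 0.612, and fry adjusted p = 0.0390), the calls of CDH6 and GFRA1 not as the mean over each gene's probes and that of GFRA1 not without background correction. Here too these checks did not cover all 4 higher genes. In the CNS neuroepithelium list 6 were higher and 5 lower of 23 (adjusted over the list alone, 6 and 5; camera adjusted p = 0.883), with a median of -0.01, a mean of 0.01 and a test pointing down. Other lists with at least 1 in 3 members called did not pass. The Schwann cell and glial precursor list had 2 higher and 1 lower of 9 (adjusted over the list alone, 2 and 1; adjusted p = 0.290). The epithelial to mesenchymal transition list had 2 higher and 2 lower of 11 (adjusted over the list alone, 2 and 2; adjusted p = 0.854). The melanocyte list had 0 higher and 2 lower of 6 (adjusted over the list alone, 0 and 2; adjusted p = 0.424). Of 11280 genes, 2358 were called, 1472 higher and 886 lower, 378 of them with 1 group below background. Without background correction 851 were called, 73.6% of them higher against 62.4%, and with an offset of 50 there were 1449.

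The comparison of sox10-NC with LSB set Wnt-induced, reporter-sorted cells beside the neuroepithelial stage of the same day. Induction, sorting and reporter differed together, so their effects cannot be told apart. Neural crest specifier genes were higher and CNS neuroepithelium genes lower as lists in sox10-NC, the first not with an estimated correlation. SOX10 was at least 45.6-fold higher (log2 6.20 ± 0.24, adjusted p = 4.26e-12) and TFAP2B at least 27.8-fold higher (5.52 ± 0.23, adjusted p = 5.79e-12). SOX10 belongs to the specifier list, and the reporter sort selects for it, so its p-value against any group is no test of the induction. The sort can also select for or against genes that vary with SOX10. The specifier and CNS list p-values therefore do not test the induction either. BGN, a small matrix proteoglycan, was 19.4-fold higher (4.28 ± 0.53, adjusted p = 6.17e-06), and ACTC1, cardiac muscle actin, 26.4-fold higher (4.72 ± 0.39, adjusted p = 4.28e-08). LHX2 was at least 32.0-fold lower (-6.05 ± 0.25, adjusted p = 4.98e-12), and FABP7, a fatty acid binding protein of radial glia, 37.8-fold lower (-5.24 ± 0.25, adjusted p = 4.03e-11).

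Neural crest specifier genes were higher for 11 of 18 measured members and lower for 1 (adjusted over the list alone, 11 and 1), with median log2 change 2.08, or 1.61 with members below background at their bounds (camera adjusted p = 1.04e-07, and adjusted p = 0.0603 with an estimated correlation). TFAP2A rose by 4.04 ± 0.37 and NR2F1, an orphan nuclear receptor, by 5.38 ± 0.52. The calls of FOXD3 (at least 2.92-fold higher) and PAX3 (at least 2.47-fold higher) ended without background correction. In the neural crest surface and migration list, 10 of 15 were higher and 2 lower (adjusted over the list alone, 10 and 2), with median log2 change 2.22, or 1.97 with members below background at their bounds (camera adjusted p = 4.99e-06, and adjusted p = 0.0603 with an estimated correlation). ERBB3 rose by 4.76 ± 0.32 and GFRA1, a GDNF family receptor, by 4.21 ± 0.37, folds that came out over 1.5 times smaller as means over each gene's probes. NGFR was 3.75-fold higher (1.91 ± 0.28), a call that also ended without background correction. CDH11, a mesenchymal cadherin, fell by 2.99 ± 0.36. The other lower member was B3GAT1, an enzyme with a part in building the HNK1 epitope. It was at least 2.49-fold lower by a probe below background in sox10-NC, except without background correction. Another B3GAT1 probe was detected on 1 of the 3 sox10-NC arrays.

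CNS neuroepithelium genes were lower for 19 of 23 members and higher for 0 (adjusted over the list alone, 0 and 19), with median log2 change -3.07, or -2.60 with members below background at their bounds (camera adjusted p = 4.44e-21, and adjusted p = 7.00e-04 with an estimated correlation). DLK1, a transmembrane protein of the Notch ligand family, was at least 187-fold lower, and HES5, a Notch effector of neural progenitors, fell by 6.13 ± 0.39. Wnt target genes were higher for 10 of 13 and lower for 1 (adjusted over the list alone, 10 and 1), with median log2 change 2.70, or 2.49 with members below background at their bounds (camera adjusted p = 1.27e-06, and adjusted p = 0.120 with an estimated correlation). Among them SP5, a zinc finger factor and direct Wnt target, was at least 10.8-fold higher and NKD1, a Wnt antagonist, at least 8.37-fold higher. SP8, a forebrain zinc finger factor on the same list, was at least 25.2-fold lower. Sensory neuron genes were higher for 4 of 7 and lower for 1 (adjusted over the list alone, 4 and 1; camera adjusted p = 0.00589, and adjusted p = 0.339 with an estimated correlation), with NEUROG1, which specifies sensory neurons, at least 8.86-fold higher. Epithelial genes were lower for 10 of 12 (adjusted over the list alone, 0 and 10), with median log2 change -1.74, or -0.76 with members below background at their bounds (camera adjusted p = 8.78e-07, and adjusted p = 0.146 with an estimated correlation), and EPCAM, an epithelial adhesion protein, fell by 3.11 ± 0.32. Immediate early genes were higher for 6 of 13 and lower for 1, along with sorting (adjusted over the list alone, 6 and 1; camera adjusted p = 0.00707, and adjusted p = 0.423 with an estimated correlation).

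Several lists did not pass the test between sox10-NC and LSB. Pan-neuronal genes were higher for 10 and lower for 4 of 21 (adjusted over the list alone, 10 and 4), with median log2 change 0.95 (adjusted p = 0.0718). ONECUT2, a homeobox factor, rose by 2.11 ± 0.32, while SYT1, the calcium sensor of synaptic vesicles, was at least 4.02-fold lower. Mesenchyme and extracellular matrix genes were higher for 5 and lower for 2 of 19 (adjusted over the list alone, 5 and 2), with median log2 change 0.52, or 0.26 with members below background at their bounds (adjusted p = 0.0636), and COL1A1, a fibrillar collagen, rose by 3.12 ± 0.29. Notch pathway genes went both ways, 7 higher and 3 lower of 15 (adjusted over the list alone, 7 and 3; adjusted p = 0.0840), with HEYL, a Notch effector of mesenchymal and smooth muscle cells, at 3.96 ± 0.29. The melanocyte list had 3 of 6 members higher (adjusted over the list alone, 3 and 0; adjusted p = 0.112), including MITF, the factor of the melanocyte lineage, at least 3.63-fold higher. BMP target genes were higher for 4 and lower for 2 of 12 (adjusted over the list alone, 4 and 2; adjusted p = 0.181), with MSX1, a homeobox factor, at 2.79 ± 0.30. The epithelial to mesenchymal transition list had 2 higher and 2 lower of 11 (adjusted over the list alone, 2 and 2; adjusted p = 0.606), with SNAI2 at 3.27 ± 0.29 and ZEB2, another repressor of CDH1, at 2.21 ± 0.31. Schwann cell and glial precursor genes were higher for 3 and lower for 3 of 9 (adjusted over the list alone, 3 and 3; adjusted p = 0.854), with a positive median and a negative mean. Integrated stress response genes were higher for 1 and lower for 2 of 15 (adjusted over the list alone, 1 and 2; adjusted p = 0.842), with a median of 0.01 and a mean of -0.09. Of 11280 genes, 2077 were called, 1102 higher and 975 lower, 502 with 1 group below background. Without background correction 707 were called and with an offset of 50 there were 1260.

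**Figure D3:**
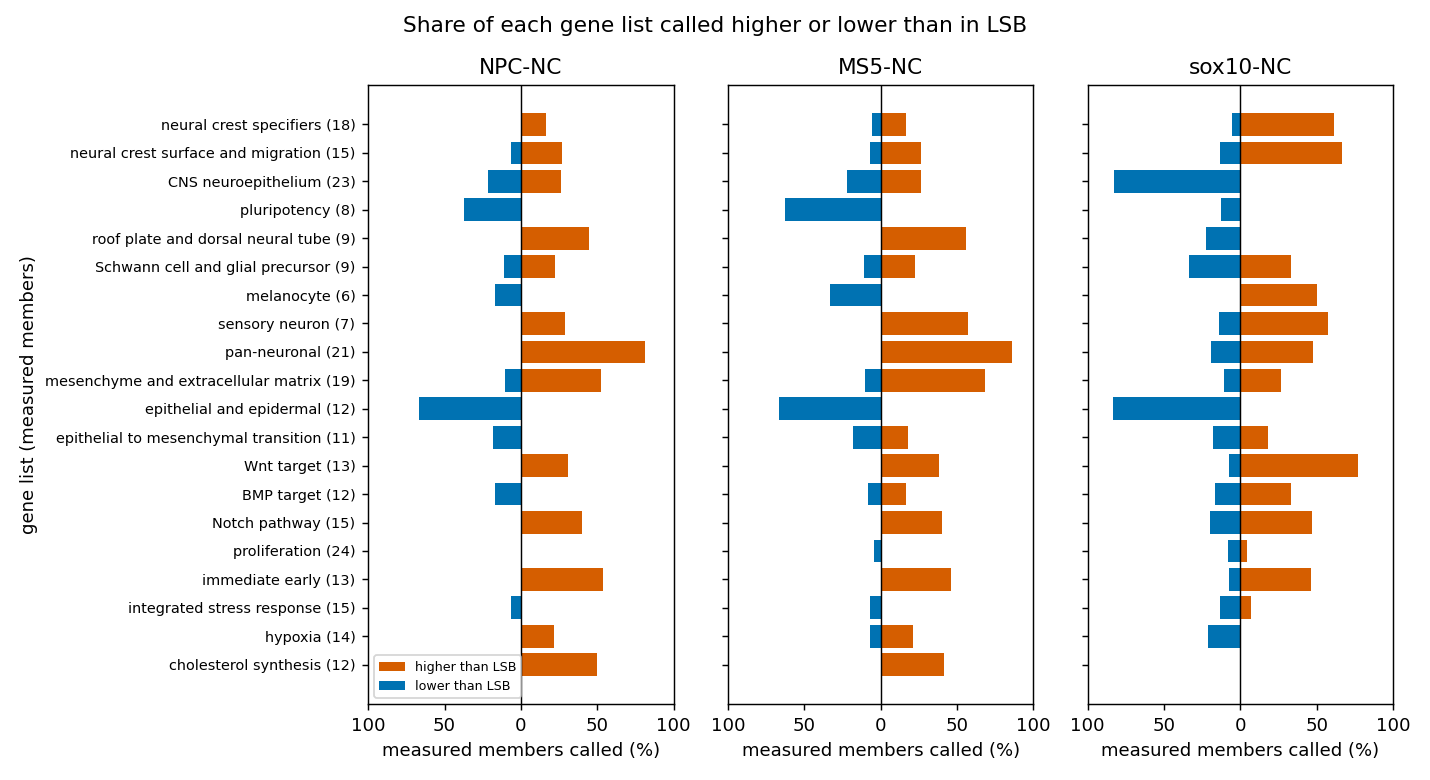
Percent of measured members called higher (right of 0) and lower (left of 0) than in LSB for each tested gene list, with 1 bar per sorted group and the number of measured members beside the list's name. CNS neuroepithelium members lie to the left for sox10-NC, with 19 of 23 lower, and on both sides for MS5-NC and NPC-NC, with 6 higher and 5 lower.

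The lists too short to test held few measured members. Of the HOX genes of paralog groups 1 to 4, 2 were measured, and HOXB2, a hindbrain HOX gene, was at least 1.28-fold higher in MS5-NC than in LSB, a call that ended without background correction and with an offset of 50. The single measured member of HOX paralog groups 5 to 13 was not called in any comparison. Of the autonomic and enteric neuron genes 3 were measured, and TH was called higher in both NPC-NC and MS5-NC than in LSB. Of the mesoderm and muscle genes 4 were measured. In the mesoderm list EOMES was higher and TNNT1, a slow muscle troponin, lower in both NPC-NC and MS5-NC than in LSB, and the TNNT1 calls ended without background correction. In sox10-NC, ACTC1 was higher than in LSB, and TNNT1, EOMES and MESP1, a factor of early mesoderm, were lower. The EOMES and MESP1 calls ended without background correction and with an offset of 50, and the MESP1 call also without LSB array 1, sox10-NC array 2 or sox10-NC array 3.

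NPC-NC was compared with MS5-NC to set the feeder-free route at day 18 beside the feeder route at day 35. Route and day changed together, so their effects cannot be told apart. The difference was small, and its largest member was GNRH1, which was 7.65-fold lower in NPC-NC (log2 -2.93 ± 0.27, adjusted p = 2.54e-05). Its level was 8.08 ± 0.26 in NPC-NC and 11.01 ± 0.40 in MS5-NC. All 3 NPC-NC arrays lay below all 3 MS5-NC arrays, as the rule for the largest falls requires. STIM2, a calcium sensor of the endoplasmic reticulum, was 3.55-fold lower (-1.83 ± 0.25, adjusted p = 0.00336), although not by the mean over its probes. GJA4, a gap junction connexin of vessels, was at least 2.27-fold higher in NPC-NC, a call that ended without background correction and with an offset of 50, and a gene that left the tested set when an NPC-NC array was left out. The other called genes were ANKRD1, a muscle ankyrin repeat protein, at least 2.42-fold higher, EFNA1, an ephrin ligand (1.56 ± 0.28), SPRY4, an inhibitor of receptor tyrosine kinase signalling (1.89 ± 0.35), DOHH, an enzyme of hypusine synthesis (-1.91 ± 0.32), MIER2 (-1.49 ± 0.26) and PPFIA2, at least 1.88-fold lower. Without background correction the calls of ANKRD1, EFNA1, SPRY4, MIER2 and PPFIA2 ended too. Those of EFNA1, SPRY4, DOHH and MIER2 ended with the authors' processed values and with only the groups compared, which also ended that of PPFIA2. The EFNA1 call ended as the mean over its probes and the PPFIA2 call with an offset of 50. With the replicate number as a block the calls of EFNA1, MIER2 and PPFIA2 ended. Of the 9 called genes, 6, 5 and 3 kept their call without MS5-NC arrays 1, 2 and 3, and 8, 3 and 3 without NPC-NC arrays 1, 2 and 3, GNRH1 and STIM2 among them each time.

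In all, 9 of 11280 genes were called between NPC-NC and MS5-NC, 4 higher and 5 lower, while 1113 had an unadjusted p under 0.05 by limma. No list had a called member, although adjusted over each list alone 1 neural crest specifier and 1 autonomic and enteric neuron gene were higher, and 1 member each of the roof plate, HOX 1 to 4, Schwann cell, sensory neuron and Wnt target lists and 2 BMP targets lower. Pan-neuronal genes had median log2 change -0.36 (camera adjusted p = 0.00191, and adjusted p = 0.471 with an estimated correlation), and pluripotency genes median log2 change 0.37 (camera adjusted p = 0.0329, and adjusted p = 0.474 with an estimated correlation). Without NPC-NC array 1 the comparison called 36 genes, without MS5-NC array 1 it called 20, and without both 120, 60 in each direction, a setting chosen after the values were seen. Leaving out MS5-NC array 3, NPC-NC array 2 or NPC-NC array 3 called 3 each, leaving out MS5-NC array 2 called 5, and array weights gave 22.

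NPC-NC was compared with sox10-NC to set 2 neural crest protocols side by side, at day 18 and day 11. Protocol, sort, reporter and day changed together, so their effects cannot be told apart. CNS neuroepithelium genes were higher and neural crest specifier genes lower as lists in NPC-NC, the second not with an estimated correlation. LHX2 was at least 79.6-fold higher (log2 7.36 ± 0.25, adjusted p = 7.73e-13) and FABP7 52.5-fold higher (5.71 ± 0.25, adjusted p = 8.13e-12). ZIC2, a zinc finger factor of the neural tube, was higher by log2 4.32 ± 0.24, adjusted p = 3.38e-10. SOX10 was at least 48.8-fold lower (-6.17 ± 0.24, adjusted p = 1.49e-12), TFAP2A 18.7-fold lower (-4.22 ± 0.37, adjusted p = 8.46e-08), and ACTC1 24.2-fold lower (-4.60 ± 0.39, adjusted p = 5.45e-08).

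CNS neuroepithelium genes were higher for 18 of 23 members in NPC-NC and lower for 0 (adjusted over the list alone, 18 and 0), with median log2 change 2.81, or 2.64 with members below background at their bounds (camera adjusted p = 2.30e-21, and adjusted p = 7.00e-04 with an estimated correlation). DLK1 was at least 169-fold higher and PAX6 at least 8.90-fold higher. Neural crest specifier genes were lower for 12 of 18 and higher for 2 (adjusted over the list alone, 2 and 12), with median log2 change -2.05, or -1.57 with members below background at their bounds (camera adjusted p = 6.11e-08, and adjusted p = 0.0603 with an estimated correlation). The higher ones were SOX9, a factor of neural crest, cartilage and glia (2.32 ± 0.30), and ZIC1, a dorsal neural tube factor, at least 4.14-fold higher. Neural crest surface and migration genes were lower for 9 of 15 and higher for 2 (adjusted over the list alone, 2 and 9), with median log2 change -1.55 (camera adjusted p = 2.03e-05, and adjusted p = 0.0603 with an estimated correlation). CDH6, a cadherin of migrating neural crest, was 12.4-fold lower, a fold over 1.5 times smaller as the mean over its probes, while B3GAT1 was higher by the probe below background in sox10-NC. NGFR was 2.73-fold lower, except without background correction or with an offset of 50.

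Pan-neuronal genes were higher for 10 of 21 in NPC-NC than in sox10-NC (over the list alone, 12 higher and 1 lower), with median log2 change 1.21 (camera adjusted p = 8.63e-06, and adjusted p = 0.339 with an estimated correlation). RTN1, a neuronal reticulon, was 17.1-fold higher. Wnt target genes were lower for 7 of 13 and higher for 1 (adjusted over the list alone, 1 and 7; camera adjusted p = 1.04e-04, and adjusted p = 0.168 with an estimated correlation), and SP5 was at least 11.5-fold lower. Roof plate genes were higher for 4 of 9 (adjusted over the list alone, 4 and 0), with median log2 change 0.79, or 0.00 with members below background at their bounds (camera adjusted p = 8.21e-04, and adjusted p = 0.147 with an estimated correlation). Cholesterol synthesis genes were higher for 7 of 12 (adjusted over the list alone, 7 and 0; camera adjusted p = 7.97e-05, and adjusted p = 0.287 with an estimated correlation), with HMGCS1, which makes the precursor of mevalonate, at 2.00 ± 0.31. Hypoxia genes were higher for 2 of 14 (adjusted over the list alone, 2 and 0; camera adjusted p = 0.0464, and adjusted p = 0.672 with an estimated correlation), with ADM, a vasodilator peptide, at 2.66 ± 0.47. Lower lists were melanocyte, 2 of 6 (adjusted over the list alone, 0 and 2; camera adjusted p = 0.00205, and adjusted p = 0.168 with an estimated correlation), sensory neuron, 4 of 7 with 1 higher (adjusted over the list alone, 1 and 4; camera adjusted p = 0.0351, and adjusted p = 0.398 with an estimated correlation), and pluripotency, 2 of 8 (adjusted over the list alone, 0 and 3; camera adjusted p = 0.0290, and adjusted p = 0.471 with an estimated correlation). Other lists with at least 1 in 3 members called did not pass. The BMP target list had 2 higher and 4 lower of 12 (adjusted over the list alone, 2 and 4; adjusted p = 0.0574). The Notch pathway list had 5 higher and 2 lower of 15 (adjusted over the list alone, 5 and 2; adjusted p = 0.424). The epithelial to mesenchymal transition list had 3 higher and 3 lower of 11 (adjusted over the list alone, 3 and 3; adjusted p = 0.611). The epithelial list had 4 higher and 2 lower of 12 (adjusted over the list alone, 4 and 2; adjusted p = 0.611). The Schwann cell and glial precursor list had 2 higher and 1 lower of 9 (adjusted over the list alone, 2 and 1; adjusted p = 0.354). Of 11280 genes, 1583 were called, 1050 higher and 533 lower, 482 with 1 group below background. Without background correction there were 569, and with an offset of 50 there were 947.

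The comparison of MS5-NC with sox10-NC set the feeder route at day 35 beside the Wnt route at day 11. Here too route, sort, reporter and day changed together. LHX2 was at least 81.8-fold higher in MS5-NC (log2 7.40 ± 0.25, adjusted p = 3.51e-13), GNRH1 32.0-fold higher (adjusted p = 1.73e-10) and RTN1 25.2-fold higher (4.66 ± 0.30, adjusted p = 1.60e-09). SOX10 was at least 46.9-fold lower (-6.30 ± 0.24, adjusted p = 1.34e-12), TFAP2B at least 28.7-fold lower (-5.36 ± 0.23, adjusted p = 7.45e-12) and TFAP2A 20.7-fold lower (-4.37 ± 0.37, adjusted p = 4.57e-08). CNS neuroepithelium genes were higher for 18 of 23 members and lower for 0 (adjusted over the list alone, 18 and 0), with median log2 change 2.53 (camera adjusted p = 1.13e-18, and adjusted p = 7.55e-04 with an estimated correlation). Neural crest specifier genes were lower for 13 of 18 and higher for 2 (adjusted over the list alone, 2 and 13), with median log2 change -2.08, or -1.88 with members below background at their bounds (camera adjusted p = 6.11e-08, and adjusted p = 0.0603 with an estimated correlation). Neural crest surface and migration genes were lower for 9 of 15 and higher for 2 (adjusted over the list alone, 2 and 9; camera adjusted p = 3.47e-05, and adjusted p = 0.0603 with an estimated correlation), and NGFR, below background in MS5-NC, was at least 3.05-fold lower, except without background correction.

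Pan-neuronal genes were higher for 15 of 21 in MS5-NC than in sox10-NC (over the list alone, 16 higher), with median log2 change 1.39 (camera adjusted p = 3.99e-07, and adjusted p = 0.287 with an estimated correlation). Roof plate genes were higher for 5 of 9 (over the list alone, 6), with median log2 change 1.03, or 0.39 with members below background at their bounds (camera adjusted p = 3.03e-05, and adjusted p = 0.0824 with an estimated correlation). Cholesterol synthesis genes were higher for 6 of 12 (adjusted over the list alone, 6 and 0; camera adjusted p = 7.38e-04, and adjusted p = 0.339 with an estimated correlation). Wnt target genes were lower for 7 of 13 and higher for 1 (adjusted over the list alone, 1 and 7; camera adjusted p = 1.45e-04, and adjusted p = 0.175 with an estimated correlation), melanocyte genes lower for 2 of 6 (adjusted over the list alone, 0 and 2; camera adjusted p = 0.00790, and adjusted p = 0.242 with an estimated correlation), and pluripotency genes lower for 3 of 8 (adjusted over the list alone, 0 and 3; camera adjusted p = 0.00155, and adjusted p = 0.362 with an estimated correlation). Other lists with at least 1 in 3 members called did not pass. The BMP target list had 2 higher and 2 lower of 12 (adjusted over the list alone, 2 and 2; adjusted p = 0.227). The Notch pathway list had 4 higher and 2 lower of 15 (adjusted over the list alone, 4 and 2; adjusted p = 0.842). The epithelial to mesenchymal transition list had 3 higher and 2 lower of 11 (adjusted over the list alone, 3 and 2; adjusted p = 0.901). The hypoxia list had 5 higher and 0 lower of 14 (adjusted over the list alone, 5 and 0; adjusted p = 0.158). The immediate early list had 4 higher and 1 lower of 13 (adjusted over the list alone, 4 and 1; adjusted p = 0.854). The mesenchyme and matrix list had 6 higher and 2 lower of 19 (adjusted over the list alone, 6 and 2; adjusted p = 0.419). The sensory neuron list had 2 higher and 4 lower of 7 (adjusted over the list alone, 2 and 4; adjusted p = 0.185). Of 11280 genes, 1955 were called, 1214 higher and 741 lower, 549 with 1 group below background. Without background correction there were 720, and with an offset of 50 there were 1200. Over all 120 list tests, 50 passed with the preset correlation and 3 of these with an estimated one, the CNS neuroepithelium list in the comparison of sox10-NC with each other group.

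Genes called the same way in all 3 sorted groups against LSB numbered 635, with 425 higher and 210 lower. ZFHX3, a homeobox and zinc finger factor, was higher by 3.66 ± 0.23 in NPC-NC, 3.73 ± 0.23 in MS5-NC and 3.84 ± 0.23 in sox10-NC. ZMIZ1, a transcriptional coregulator, was higher by 2.73 ± 0.25, 2.95 ± 0.25 and 3.04 ± 0.25, and POLR2A, the large subunit of RNA polymerase II, by 2.65 ± 0.26, 2.74 ± 0.26 and 2.75 ± 0.26. ANXA1 changed by -3.80 ± 0.31, -3.24 ± 0.31 and -3.09 ± 0.31, and BBS9, a ciliary trafficking protein, by -2.31 ± 0.27, -2.51 ± 0.27 and -2.65 ± 0.27. The 3 comparisons share the LSB arrays. As LSB was also the only unsorted group, the shared genes differed along with sorting. Simulated groups without changes shared 0 genes in 100 simulations, a value that leaves out the effects, and independent lists of the same sizes would share 14.7 higher and 3.71 lower, values that leave out the shared arrays. Part of the excess may come from the shared LSB arrays. Across genes, the changes in NPC-NC and MS5-NC correlated at 0.919, against 0.50 in simulated groups without changes, with a covariance of 0.636 against 0.0372. Those in NPC-NC and sox10-NC correlated at 0.4997, against 0.501, with a covariance of 0.352 against 0.0373. NPC-NC and MS5-NC shared 993 higher and 413 lower genes with 0 in opposite directions, and NPC-NC and sox10-NC shared 477 higher and 249 lower with 75 in opposite directions. Without background correction 185 genes were shared by all 3, and with an offset of 50 there were 349.

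The genes that set NPC-NC apart from both MS5-NC and sox10-NC were EFNA1, GJA4, ANKRD1 and SPRY4, all higher in NPC-NC. Against sox10-NC, EFNA1 was 3.82-fold higher (1.93 ± 0.28, adjusted p = 5.13e-05). Independent lists of the same sizes would share 0.372 higher and 0.236 lower genes, and simulated groups without changes, a value that leaves out the effects, shared 0. The count fell to 0 without background correction and without NPC-NC array 3, to 1 without NPC-NC array 2 or MS5-NC array 3, and came to 10 without NPC-NC array 1. It was 29 without both NPC-NC array 1 and MS5-NC array 1.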

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

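The splits of the arrays were planned, and the other tests of explanations here, with the check of the splits' spread, were chosen only after the results were seen. Single outlying arrays were not tested for in groups of 3 arrays.

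Neural crest and CNS gene lists differed between sox10-NC and both NPC-NC and MS5-NC when each was set against LSB, by the direct camera test between the groups. Sort, reporter and day changed along with induction, so these differences cannot be credited to induction. Median log2 changes are given as NPC-NC minus sox10-NC and MS5-NC minus sox10-NC in turn, with the adjusted p at the preset correlation. They were −2.05 (6.11e-08) and −2.08 (6.11e-08) for neural crest specifiers, −1.55 (2.03e-05) and −2.03 (3.47e-05) for neural crest surface and migration, and 2.81 (2.30e-21) and 2.53 (1.13e-18) for CNS neuroepithelium. With an estimated correlation, adjusted p = 7.00e-04 and 7.55e-04 for the CNS list and 0.0603 for each of the other 4 tests. Pan-neuronal genes differed by 1.21 (8.63e-06) and 1.39 (3.99e-07), roof plate genes by 0.79 (8.21e-04) and 1.03 (3.03e-05), and cholesterol synthesis genes by 1.17 (7.97e-05) and 1.07 (7.38e-04). Melanocyte genes differed by −0.94 (0.00205) and −0.65 (0.00790), and pluripotency genes by −0.39 (0.0290) and −0.76 (0.00155). Sensory neuron genes differed by −1.97 (0.0351) and hypoxia genes by 0.73 (0.0464) for NPC-NC minus sox10-NC, and went the same way, by −1.65 (0.185) and 0.45 (0.158), for MS5-NC minus sox10-NC. The direct tests between NPC-NC and MS5-NC did not pass for these 2 lists (0.0937 and 0.537). With an estimated correlation the passing tests of these 7 lists had adjusted p = 0.0824 to 0.672.

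The first pattern is that arrays of the sorted MS5-NC and NPC-NC groups carried forebrain and neuronal genes, the neuronal ones higher in part in sox10-NC too (10 of 21 higher and 4 lower than in LSB), without SOX10, FOXD3 or TFAP2B above background, although 4 of 15 neural crest surface and migration genes were higher than in LSB in each. Probes that fail to report neural crest genes were argued against, since 8 of the 8 tested neural crest genes of the marker panel were detected on all 3 sox10-NC arrays. An exchange of single arrays with LSB or sox10-NC arrays was argued against too. The highest correlation of an MS5-NC or NPC-NC array with those groups was 0.912, and the lowest among MS5-NC and NPC-NC arrays 0.947. An exchange of a whole group keeps its arrays together, so these correlations cannot exclude it. NGFR, which encodes the sorted p75, was above background on 2 of the 6 arrays. Neither it nor B3GAT1, which has a part in building the HNK1 epitope, was called higher than in unsorted LSB. The sort read a receptor protein and a carbohydrate while the arrays measured RNA, so low RNA does not show that these were absent. On these values, RNA of another population than the label names stays open. A biological candidate explanation, that the route and the day give CNS cells that pass the gate, cannot be told apart from it: no array measured cells before the sort, and B3GAT1, although at least 3.49-fold higher in both than in sox10-NC by a probe below background there, with another probe detected on 1 sox10-NC array, differed from LSB by 0.69 ± 0.26 in NPC-NC and 0.49 ± 0.26 in MS5-NC (adjusted p = 0.0570 and 0.151), so that enrichment by the gate was not shown.

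The second pattern is that MS5-NC and NPC-NC hardly differed, with NPC-NC array 1 near the MS5-NC arrays. Without NPC-NC array 1, picked because it lay away from NPC-NC arrays 2 and 3, the comparison called 36 genes against 9 (at most 20 without any other array), and a larger difference hidden by this array cannot be told apart from the narrower spread that its removal brings. An exchange of NPC-NC array 1 with MS5-NC array 1 cannot be told apart from a spread between cultures. GNRH1 went with the labels, at 7.78 on NPC-NC array 1 and 10.74 on MS5-NC array 1. It was the largest called change under these labels. On the first principal component NPC-NC arrays 1 to 3 lay at −32.9, −28.7 and −30.5 and MS5-NC arrays at −39.0, −43.1 and −48.1. On the second they lay at −7.23, −3.04 and −1.45 and at −10.9, −12.0 and −14.9. Both components went with the labels, while on the third NPC-NC array 1 lay with MS5-NC arrays 2 and 3. MS5-NC array 1 correlated better with its own group than with NPC-NC arrays 2 and 3 by 0.00266, within the SD of 0.00713 among correlations inside these groups, and exchanging the labels called 38 genes. Both tests were changed after their values were seen: a first version of the exchange test used the correlation alone and would have argued against the exchange, and a first version of the other test would have favoured a hidden difference.

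The third pattern is that immediate early genes were higher in the sorted groups than in unsorted LSB. In all 3 sorted groups 5 genes were called higher, FOS, JUN, EGR1, DUSP1 and KLF6. Dissociation and sorting could raise such genes, and this cannot be told apart from the cell type, because LSB alone was unsorted. Between sorted groups the list did not pass the test, with adjusted p = 0.166 for NPC-NC against MS5-NC, 0.718 for NPC-NC against sox10-NC and 0.854 for MS5-NC against sox10-NC.

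The 6 arrays of a comparison allow 10 splits into equal groups, too few for a share under 0.05. The real split called 1696 genes for NPC-NC and LSB, 2358 for MS5-NC and LSB, 2077 for sox10-NC and LSB, 1583 for NPC-NC and sox10-NC, and 1955 for MS5-NC and sox10-NC. The highest other split called 0, 0, 0, 1 and 0 genes, so that 1 of 10 splits reached the real count in each. For NPC-NC and MS5-NC 2 of 10 splits reached the real count of 9, and the split that put MS5-NC array 1 with NPC-NC arrays 2 and 3 called 38, which points to a structure of the samples beside the groups. Of 100 splits of the 12 arrays, the real one included, 1 shared as many genes as the real 635, and the highest other, with the sox10-NC arrays in the place of LSB, shared 571. Of 100 splits of the 9 sorted arrays, 3 set apart at least 4 genes, the real one included. The highest, 1375, had the sox10-NC arrays in the place of NPC-NC, and the next, 21, had MS5-NC arrays 2 and 3 with NPC-NC array 1. Such high counts point to a structure of the samples. Splits that mix groups widen the spread within groups, here to a median of 1.43 and 1.23 times that of the real groups, and 97 and 92 of the 99 other splits gave 0. At 0.05 the splits speak for the shared count only against arrays that fall into no groups. With the sox10-NC arrays in the place of LSB 571 genes were still shared, so the splits show no sharing particular to the sorted groups. Nor do they show what the shared LSB arrays add. For the 4 genes set apart chance is left open, since 2 of 10 splits of the NPC-NC and MS5-NC arrays alone reached the real count.

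Probes without a gene in the annotation also differed between groups. Of 3637 detected unnamed probes, 435 were called between NPC-NC and LSB and 469 between sox10-NC and LSB, smaller shares than the 14.2% and 17.8% of named probes.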

How the results depend on the processing

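The setting that left out NPC-NC array 1 and MS5-NC array 1 together was chosen only after the results were seen, and all others were planned. No list that passed the test and no named gene that was called reversed its direction in the settings where it was tested. The direction of the other lists and named genes was not checked. Between NPC-NC and MS5-NC the balance of 4 higher and 5 lower genes became 3 and 2 without MS5-NC array 2. Counts are given in the order NPC-NC and LSB, MS5-NC and LSB, sox10-NC and LSB, NPC-NC and sox10-NC, MS5-NC and sox10-NC, and shared by all 3, where 1696, 2358, 2077, 1583, 1955 and 635 genes were called. Without background correction they were 533, 851, 707, 569, 720 and 185, with an offset of 50 950, 1449, 1260, 947, 1200 and 349, and with no minimum fold 3231, 4358, 3757, 2497, 3296 and 1478. The last follows from the looser threshold, and the others go with smaller folds, at a median of 0.577 times the reported fold without background correction and 0.772 times with an offset of 50, over 286 named folds. In the other settings these 6 counts stayed within 1.5 times, and with 1 array left out they ranged over 1520 to 1795, 2188 to 2469, 1936 to 2179, 1535 to 1662, 1878 to 2086 and 538 to 690.

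NPC-NC and MS5-NC, with 9 genes called, gave 3 without background correction, 4 without a detection filter, 22 with array weights, 4 at an adjusted p under 0.01, 4 with only the groups compared, 3 to 36 with 1 array left out, and 120 with NPC-NC array 1 and MS5-NC array 1 both left out. Genes set apart in NPC-NC, 4 in all, came to 0 without background correction, 2 with the authors' processed values, 1 without a detection filter, 8 with array weights, 2 at an adjusted p under 0.01, 0 to 10 with 1 array left out, and 29 with both arrays left out. Apart from the stricter threshold, the cause was not tested. Gene list shifts numbered 50, with 3 kept by camera with an estimated correlation, 62 passing by fry, and 48 to 54 with 1 array left out. Of 374 named calls, 80 were lost in at least 1 of the settings checked for named genes. Not checked were no minimum fold, an adjusted p under 0.01, no detection filter, array weights, and both arrays left out. A call was not counted as lost where its gene was no longer tested. Of the 9 calls between NPC-NC and MS5-NC, 4 were kept at an adjusted p under 0.01 and 3 without a detection filter.

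With the replicate number as a block the counts were 1703, 2359, 2084, 1582, 1956 and 638, with 6 between NPC-NC and MS5-NC and 3 set apart. Over 18 pairs of arrays with the same number, correlations after removal of the group means were −0.0878 to 0.179, with 2 over 0.1. Both were between NPC-NC and sox10-NC, at 0.179 for array 1 and 0.148 for array 2, against −0.0074 for array 3. Arrays with unlike numbers were not compared, so a pairing of these groups is left open. A block for the chip was not run, since no chip is given. Signal over background limits what can be seen, since a gene below background in a group has a lower bound as its fold.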

Other observations

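All lists and tests here were chosen only after the results were seen. The dorsal telencephalon and metallothionein lists were written after EOMES, EMX2, FEZF2, LHX2 and MT1F had been seen called in the same comparisons, so their camera p-values describe the lists and carry no weight as tests. Genes of the dorsal telencephalon and of cortical excitatory neurons were higher in MS5-NC and NPC-NC than in LSB, for 10 and 9 of 14 measured members and with 0 lower. The median log2 changes were 2.38 and 1.80 (camera, adjusted p = 3.07e-09 for both, and adjusted p = 0.00283 for both with an estimated correlation). The members called in both were EMX2, EOMES, FEZF2, LHX2, NFIB, RELN, SLC17A6, SLC17A7 and TBR1, among them the vesicular glutamate transporters SLC17A6 and SLC17A7 and TBR1, a factor of deep cortical layers. In sox10-NC 1 member was higher than in LSB and 6 lower, with a median of −0.50 (adjusted p = 0.0218, and adjusted p = 0.108 with an estimated correlation). The fixed CNS neuroepithelium list also holds EMX2, FEZF2 and LHX2. Genes of the ventral telencephalon and inhibitory neurons were higher for 4 of 5 members in MS5-NC and 3 of 5 in NPC-NC (adjusted p = 0.00272 and 0.00183, and adjusted p = 0.193 and 0.185 with an estimated correlation), including GAD1, which makes the transmitter GABA. Midbrain and hindbrain genes, with 6 measured, had 0 higher and 1 lower member in MS5-NC and 1 higher and 1 lower in NPC-NC (adjusted p = 0.264 and 0.824).

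Metallothionein genes, which bind zinc and copper, were lower than in LSB for 6 of 7 members in each sorted group. As LSB was the only unsorted group, these genes too differed along with sorting. The median log2 changes were −3.72 in NPC-NC, −3.89 in MS5-NC and −3.57 in sox10-NC (camera, adjusted p = 2.37e-08, 6.39e-07 and 1.41e-06). With an estimated correlation, adjusted p = 0.0446, 0.0542 and 0.0555. The 6 members were MT1E, MT1F, MT1G, MT1H, MT1X and MT2A.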
